A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

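RNA from budding yeast, Saccharomyces cerevisiae, of the laboratory strain BY4741 was compared on two-colour arrays, on which a pair of RNAs labelled with Cy3 and Cy5 bind the same spots. The 2 comparisons were an msg5 deletion against wild type, and the msg5 deletion with alpha factor against the same deletion without it. MSG5 encodes a dual-specificity phosphatase that acts on mitogen-activated protein kinases (MAPKs), and alpha factor is the mating pheromone sensed by a cells. Per the labels, cells were grown in rich medium at 24 °C with shaking at 200 rpm and diluted to an optical density of 0.2. For the first comparison they grew for 2 h 30 min and were collected 2 h later. For the second they grew for 4 h and were collected after 90 min, with alpha factor at a concentration the labels give as 50 mM in the treated culture. Whether the unit in the labels is the one meant could not be checked here.

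Per the labels, the arrays were scanned and segmented with GenePix Pro 5.0. Each comparison rested on 4 arrays from 2 biological samples with swapped dyes, which the authors condensed into a single value per feature. The deposited values are log ratios, taken here as log2 on the grounds given below, with 1 value per feature and comparison, no spread between replicates and no p-value. Values of single arrays, spot intensities and signal over background were not used here. The normalization, any filter and the genome build are not given in the sources used here. Gene medians of the deposited log2 ratios were -0.07 for the deletion and -0.05 for alpha factor.

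The scale was read from the values. In the deletion comparison, 100% of 5310 values were base 2 logarithms of ratios rounded to 0.001, within 5.5e-05, where chance placement gives 7.52%. In the alpha factor comparison no such grid held. Of its 705 values below -0.3, 79.1% were base 2 logarithms of ratios rounded to 0.0001, where chance gives 54.3%, against 70.6% and 67.7% for natural logarithms and 81.8% and 81.0% for base 10. The base of the alpha factor values is thus less certain, and their folds hold only if it is 2. Direction was taken as deletion over wild type from the title of that sample, and MSG5 was the lowest feature there. For alpha factor the direction is likely treated over untreated. The basis is that the channel layout is the same in both samples and that 6 of 7 pheromone-induced genes named as a check before the data were examined lay above 0. Turning the sign would reverse every direction given for that comparison.

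The table held 6209 rows, of which 2 were controls and 6207 were gene features. Against the names of the R64 assembly, 5654 features matched by locus tag and 57 through an older name, and 496 had no symbol. The R64 table was used for names, for which genes are neighbours and, in an alternative chosen after seeing the data, for gene length. That length is the genomic span with introns, and whether it matches the build behind the arrays is unknown. Features of the same gene were averaged, giving 4969 genes with a value in the deletion comparison, 4597 in the alpha factor comparison and 4378 in both. Missing features made up 14.5% and 21.4%. Where genes had several features, these differed by a median of 0.20 in log2 over 25 genes in the deletion comparison and 0.29 over 24 genes with alpha factor, and by at most 0.61 and 0.68. The control features gave another view of error: the Arabidopsis control stood at 0.19 in the deletion comparison and 0.12 with alpha factor, and the 3XSSC control at -0.01 and 0.22. Several list medians called apart below are no larger than these, but each control is a single feature and does not give the error of a median over many genes.

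Genes were counted as higher or lower at a change of at least 2-fold (a log2 ratio of 1 or -1). Each of 25 gene lists with at least 5 measured members was described by the percentile of its median among 10000 random lists of the same size from all measured genes, and called apart at or below 2.5 or at or above 97.5. The random lists were not matched on mean expression, since no intensities were used. Percentiles describe these arrays and are not p-values. Gene length was not controlled for in these percentiles. An alternative drew random lists matched on length in 10 groups, for which 100% of the members of each list had a length. Simulated lists, 40 per setting, held genes picked at random from shuffled values, with all members shifted alike. In the deletion comparison a shift of 0.3 was called in 97.5% of lists of 10 genes and 100% of lists of 30. With alpha factor it was called in 95% and 100%. A shift of 0.1 was called in 35% and 65%, and in 17.5% and 52.5%. With no shift, 2.5% to 5% were called high and 0% to 2.5% low. Members of these lists vary independently, so the rates may not hold for real lists whose genes vary together.

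The size rule, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were MSG5 with 2 neighbours on each side, the 12 highest and 12 lowest values per comparison, up to 4 members of each list with the largest absolute value, and 5 genes for each way in which a pair of values can lie. Other genes are named as members of small counts or groups, chosen after their values were seen. Alternatives covered other size rules, centring, single features, unnamed features, other list statistics and other random lists. Matching on gene length, adjustment for the position of a feature in a cycle of 384 rows, leaving out MSG5 from the lists that hold it and differences of list values between comparisons were chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.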

Results

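The series held 2 samples, each a set of condensed log2 ratios from 4 two-colour arrays, for a yeast strain lacking the MAPK phosphatase MSG5. The first sample set the deletion against wild type, and the second set alpha factor against no alpha factor within the deletion. Values were present for 5308 and 4877 of the 6207 gene features. There is 1 value per gene and comparison, so no difference below was tested against replicates, and the number of arrays limits the precision.

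The first comparison asked which transcripts differ when MSG5 is missing and no pheromone is added. MSG5 itself had a log2 ratio of -2.51, the lowest of all features. Genes of mating were the highest named genes: FIG1, a membrane protein of calcium uptake during mating, was 10.1-fold higher in the deletion (log2 ratio 3.33), FIG2, a cell wall adhesin of mating cells, was higher by 2.82, and AGA1, the anchor subunit of a-agglutinin, by 2.02. SLT2, the MAPK of the cell wall integrity pathway, was higher by 1.42. Among 4969 measured genes, 39 were at least 2-fold higher and 13 at least 2-fold lower.

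Of 31 measured pheromone response genes, 10 were at least 2-fold higher and 3 at least 2-fold lower, and their median of 0.43 lay at percentile 100 of random lists. The higher members included the pheromone-regulated membrane proteins PRM6 (1.96), PRM1 (1.82) and PRM3 (2.84-fold), the a-specific gene ASG7 (1.87), AGA2 (1.26), the binding subunit of a-agglutinin, and MFA1 (1.03), a gene for a-factor. The lower members were MSG5, PRM10 (-1.16) and KAR3 (-1.37), a kinesin of nuclear fusion. FUS1, a protein of cell fusion, had a value of 0.66 and FUS3, the mating MAPK, 0.38. The pathway components as a list had a median of 0.04 at percentile 96.9, within the random range, with KSS1, the filamentation MAPK, at -0.73. Among alpha-cell genes, markers of the other mating type, SAG1, of alpha-agglutinin, was higher by 1.17 and the alpha-factor gene MF(ALPHA)2 had a value of 0.42; with 4 measured members that list was too small to test.

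Cell wall integrity output genes had the highest median of the lists tested, 0.54 at percentile 100. Of 34 members, 6 were at least 2-fold higher, none was 2-fold lower, and 31 lay above the median of all genes. PRM5 was 2.83-fold higher. NCW2, a cell wall protein, was higher by 1.19 in log2, SPI1, a cell wall protein induced by weak acids, by 1.16, KDX1, a kinase related to SLT2, by 1.10, and YPS3, a yapsin protease, by 1.10. RLM1, the transcription factor downstream of SLT2, had a value of 0.79 and PTP2, a tyrosine phosphatase of MAPKs, 0.90. The pathway's own components had a median of 0.05 at percentile 96.4, within the random range, although their mean of 0.18 lay at percentile 99.4. Neither the high osmolarity pathway components (median -0.06, percentile 53.8) nor the osmotic stress genes (0.02, percentile 88.5) stood apart.

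General stress genes had a median of 0.38 at percentile 100, with TPS2 and TSL1 of trehalose synthesis at 0.94 and 0.91, SOL4 at 0.86 and the small chaperone HSP42 at 0.83. No member reached 2-fold, and 30 of 33 lay above the median of all genes. Respiration genes (0.18, percentile 100), glycolysis and fermentation genes (0.09, percentile 99.3) and amino acid starvation genes (0.08, percentile 99.98) also lay high. In these lists SDH4, of succinate dehydrogenase, had a value of 0.54, the glycolytic kinase PGK1 0.82, and ARG1, of arginine synthesis, 1.44. The glycolysis list left the outer range when its mean was used (percentile 97.2).

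Lists of growth and division lay low. Ribosome biogenesis genes had a median of -0.22 at percentile 0, with UTP8 at -0.74, whereas cytosolic ribosomal proteins (-0.04, percentile 90.5) did not stand apart. G1/S genes had a median of -0.23 (percentile 0), with SPT21, a regulator of histone genes, at -0.73 and the replication factor CDC45 at -0.69. G2/M genes lay at -0.32 (percentile 0.01), with HST3, a histone deacetylase, at -0.66 and IQG1, of cytokinesis, at -0.65. Histone genes lay at -0.25 (percentile 2.02), but at percentile 2.85 by their mean. Iron genes had a median of -0.37 (percentile 0), with the cell wall mannoproteins FIT3 and FIT2 at -1.38 and -0.87, and phosphate genes lay at -0.29 (percentile 0.115), with the transporter PHO84 at -0.82. M/G1 genes had a median of -0.06 (percentile 54.2). Filamentation genes lay at -0.06 (percentile 54.9), but at percentile 1.94 without their member farthest from 0, PTP2. Their median then jumped across a gap in the middle of the list, from NFG1 (0.12) to PHD1 (-0.23), as it would without any member above the gap. MAPK phosphatases (-0.03, percentile 70.1), methionine and sulfur genes (-0.10, percentile 26.7), sterol genes (-0.07, percentile 49.2), hexose transporters (-0.01, percentile 71.3) and subtelomeric families (-0.03, percentile 82.1) did not stand apart.

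Outside the lists, the transketolase gene TKL2 had a log2 ratio of -1.84, RCL1 of ribosomal RNA processing -1.31, GCN1 of the starvation response -1.28, CDC73 of the Paf1 complex -1.16, COQ2 of coenzyme Q synthesis -1.15 and MEX67 of mRNA export -1.06. FMP27 was higher by 1.66. CDC73 (-0.95) and PRM10 (-0.80) no longer reached 2-fold after adjustment for feature position, nor did MEX67 (-0.99) after centring. Features without a symbol or settled function among the extremes were YIL082W (2.97) and YIL080W (2.16), both of the Ty3 retrotransposon, YBR012W-A (1.57), of Ty1, and YCRX18C (1.88), and on the low side YNL198C (-2.04) and YDR401W (-1.42). The genes beside MSG5 on the chromosome, POR1 (0.43), VAC7 (-0.19), COX5A (-0.08) and COG5 (-0.22), were all within 1.5-fold. Of 24 lists tested, 12 stood apart, where 1.2 would by chance if the members of each list varied like genes drawn at random. Members that vary together would make such calls more frequent.

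**Figure D1:**
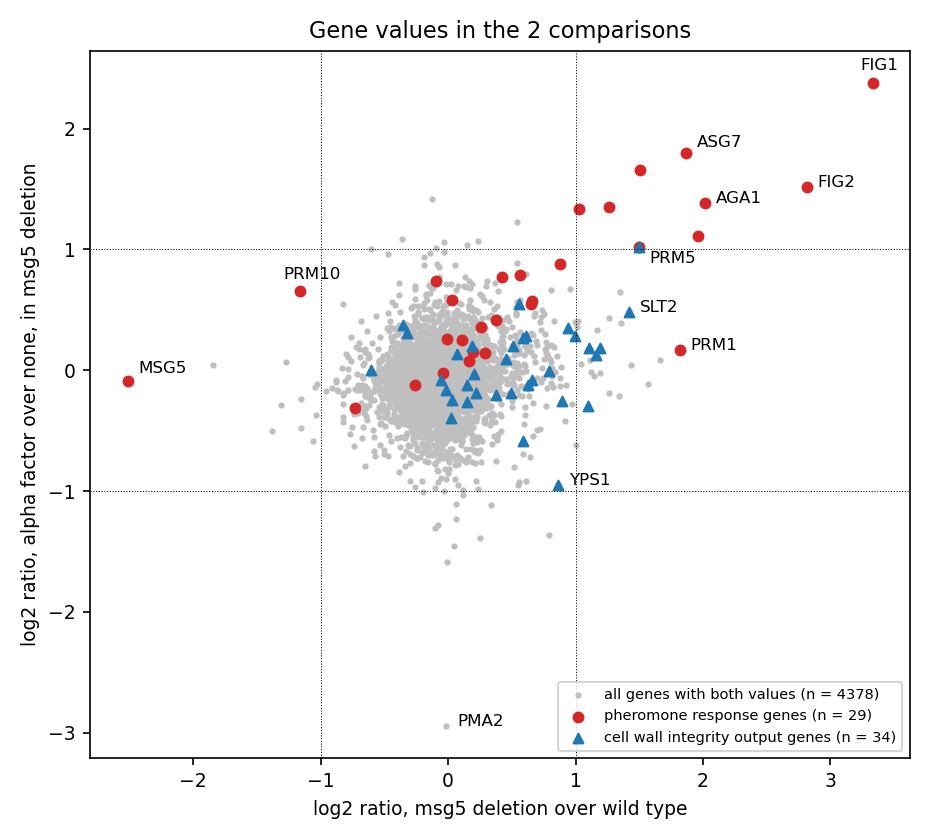
Log2 ratio of alpha factor over none in the msg5 deletion (vertical) against log2 ratio of the deletion over wild type (horizontal) for 4378 genes with both values, one point per gene. Red circles are 29 pheromone response genes and blue triangles 34 cell wall integrity output genes, dotted lines mark a 2-fold change, and 9 genes lie above it in both comparisons.

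The second comparison asked how cells without MSG5 respond to alpha factor, with values likely given as treated over untreated. FIG1 was again the highest gene, higher by 2.38, followed by ASG7 at 1.80, PRM3 at 1.66 and FIG2 at 1.52. AGA1, AGA2 and MFA1 were higher by 1.39, 1.35 and 1.34. Histone genes and genes of G2/M lay low, with the histone H3 gene HHT1 at -0.85 and the mitotic cyclin gene CLB2 at -0.70. Among 4597 genes, 17 were at least 2-fold higher and 12 at least 2-fold lower. MSG5 had a value of -0.09, which checks nothing, since the gene was deleted in both RNAs.

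Pheromone response genes had a median of 0.57 at percentile 100, with 9 of 31 at least 2-fold higher and none 2-fold lower. That the list lay high, not low, is partly fixed by the choice of direction, since all 7 genes used to check it are members. PRM6 was higher by 1.11 and PRM5 by 1.02, KAR4, a transcription factor of mating, had a value of 0.88, GPA1, the G protein alpha subunit, 0.58, and FUS1 0.57. PRM1 had a value of 0.17, FUS2 of -0.18 and PRM2 of -0.73. After adjustment for feature position PRM5 (0.99) fell just short of 2-fold. Cell wall integrity output genes did not stand apart, with a median of -0.00 at percentile 86.4. In that list only PRM5 reached 2-fold, SLT2 had a value of 0.48, CRH1, a chitin transglycosylase, 0.55, and the yapsin gene YPS1 -0.95. General stress genes (-0.11, percentile 13.0) did not stand apart either, although YGP1, a secreted glycoprotein, was at -1.11.

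Histone genes had a median of -0.43 (percentile 0.01), with HHT2 at -0.73 and HHF2, for histone H4, at -0.65. G2/M genes lay at -0.23 (percentile 0.46), with HST3 at -0.80 and ALK1 at -0.70. M/G1 genes lay at -0.23 (percentile 0.36), with EGT2, of cell separation, at -0.89 and SIC1, an inhibitor of cyclin-dependent kinase, at -0.74. G1/S genes had a median of 0.01 (percentile 91.9), with the cyclin PCL2 at 0.63 and CTF18 at -0.71. Amino acid starvation genes lay low (-0.17, percentile 0.255), with ILV5 at -0.51, but at percentile 4.12 against random lists matched on gene length, which ended the call. Phosphate genes also lay low (-0.20, percentile 1.64), but were within the random range by their mean (percentile 6.91) and against lists matched on length (percentile 2.68). Iron genes, at -0.16 and percentile 3.95, did not stand apart, nor did ribosome biogenesis genes (-0.06, percentile 42.7) or respiration genes (0.00, percentile 91.0).

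Cytosolic ribosomal proteins lay high with a median of 0.11 (percentile 100), although none of the 133 list members reached 1.5-fold and RPL42B was the farthest at 0.43. That list was picked by the start of gene names, so it can hold a gene of other function. Subtelomeric families had a median of 0.07 (percentile 99.75), with PAU20 at 1.08 and AAD15 at 1.01, of which PAU20 (0.99) fell short of 2-fold after adjustment for feature position. Across 4597 genes, values with alpha factor went with gene length (Spearman's rho -0.23). Against random lists matched on length, ribosomal proteins stayed at percentile 100, but lay at percentile 97.2 against lists from the shortest of 10 length groups, whose median was 0.09. Subtelomeric families went to percentile 92.2 against matched lists, which ended their call. A list of 6 measured alpha-cell and diploid genes lay at 0.16 (percentile 97.7), but at percentile 61.4 without its member farthest from 0, the meiotic recombinase gene DMC1 (0.58). The median then fell to -0.02, across a gap in the middle of the list below SAG1 (0.34), as it would without any member above the gap.

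The lowest features with alpha factor were YGR160W (-3.38), PMA2 (-2.94), a plasma membrane proton pump, YDL023C (-1.96), YJR071W (-1.73) and YBL100C (-1.68). DAL80, a repressor of nitrogen genes, stood at -1.58, YGL199C at -1.55, VBA5 at -1.45, DYN1, the dynein heavy chain, at -1.39, CAF4 at -1.36, NBA1 at -1.31 and YSR3 at -1.28. HFA1, a mitochondrial acetyl-CoA carboxylase, was higher by 1.23 and YGR018C by 1.42. Of 25 lists tested, 9 stood apart, where 1.25 would by chance if the members of each list varied like genes drawn at random. Here too, members that vary together would raise the number of calls.

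**Figure D2:**
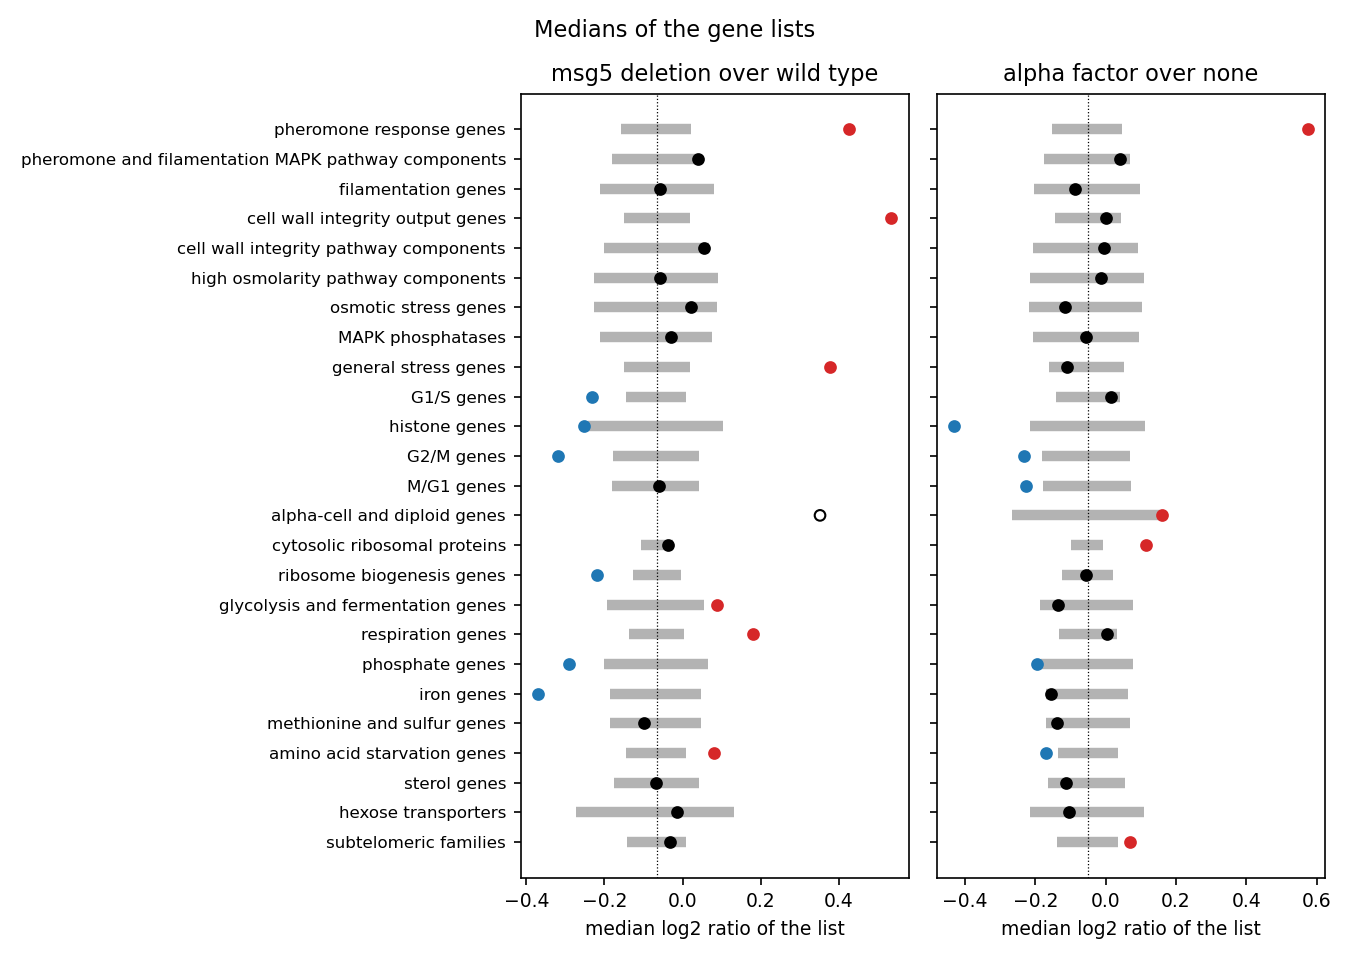
Median log2 ratio of each of the 25 gene lists (points) with the central range of medians of 10000 random lists of the same size (grey bars, the range within which a list was not called apart), for the deletion over wild type (left) and alpha factor over none (right). Red and blue points lie above and below that range, the open point is a list too small to test, dotted lines mark the median of all genes, and cell wall integrity output genes stand at 0.54 on the left and -0.00 on the right.

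Set side by side, 9 genes were at least 2-fold higher in both comparisons: AGA1, AGA2, ASG7, FIG1, FIG2, MFA1, PRM3, PRM5 and PRM6. Independent lists of the same sizes (32 and 17 of 4378 genes) would share 0.124. All 9 are members of the pheromone response list, and FIG1 and AGA1 are among the genes used to check the direction. None was 2-fold lower in both, and the genes lowest in both were HST3 (-0.66 and -0.80), UTP8 (-0.74 and -0.63), MEX67 (-1.06 and -0.59), UBA3 (-0.58 and -0.67) and RIO1 (-0.57 and -0.71). At 1.5-fold, 3 genes were lower in both, where 2.90 would be if the comparisons were independent. Across 4378 genes, which are not independent replicates, Pearson's r was 0.18 and Spearman's rho 0.11, and r was 0.10 without the pheromone response list. With the sign of the alpha factor values turned, the 9 genes would lie opposite ways and r would be -0.18.

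At 1.5-fold, 6 genes were higher in the deletion and lower with alpha factor, where 3.69 would be if independent, and 2 lay the other way, where 1.39 would be. The genes with the largest opposite values were, on one side, YPS1 (0.86 in the deletion and -0.95 with alpha factor), CAF4 (0.79 and -1.36), HAP4, an activator of respiration genes (0.64 and -0.72), SIR4, a silencing protein (1.00, or 0.94 after adjustment for feature position, and -0.62), and YRO2 (0.61 and -0.92). After the same adjustment CAF4 reached 2-fold in the deletion (1.01). On the other side were PRM10 (-1.16 and 0.65), TAD1, a transfer RNA deaminase (-0.61 and 1.00), CIS1 (-0.82 and 0.55), YNR025C (-0.49 and 0.49) and DFP2 (-0.47 and 0.47). The difference between the comparisons, gene by gene, had a median of 0.42 for cell wall integrity output genes and 0.43 for general stress genes, both at percentile 100 of random lists. It was 0.27 for amino acid starvation genes (percentile 100) and 0.27 for glycolysis genes (percentile 99.8), and low for ribosomal proteins (-0.19, percentile 0), ribosome biogenesis genes (-0.20, percentile 0.01), iron genes (-0.33, percentile 0.03) and subtelomeric families (-0.14, percentile 1.84). Pheromone response genes had a difference of -0.04 (percentile 33.4). With the sign of the alpha factor values turned, the medians were 0.45 for cell wall integrity output genes, 0.22 for general stress genes and 1.20 for pheromone response genes, all at percentile 100, and amino acid starvation genes (percentile 72.3) and glycolysis genes (percentile 47.4) no longer stood apart. Ribosomal proteins (0.07, percentile 100) and subtelomeric families (0.07, percentile 99.8) then lay high, whereas ribosome biogenesis genes (-0.24, percentile 0.93) and iron genes (-0.54, percentile 0) still lay low. Some lists stood apart only with the sign turned. Histone genes (-0.69, percentile 0.01), G2/M genes (-0.59, percentile 0) and phosphate genes (-0.43, percentile 0.16) then lay low. Respiration genes (0.20, percentile 100) and the components of the pheromone and filamentation pathways (0.12, percentile 99.4) and of the cell wall integrity pathway (0.13, percentile 98.0) lay high. These differences were computed after the separate values had been seen, rest on base 2 in both columns, and set side by side cultures with other growth and collection times.

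**Figure D3:**
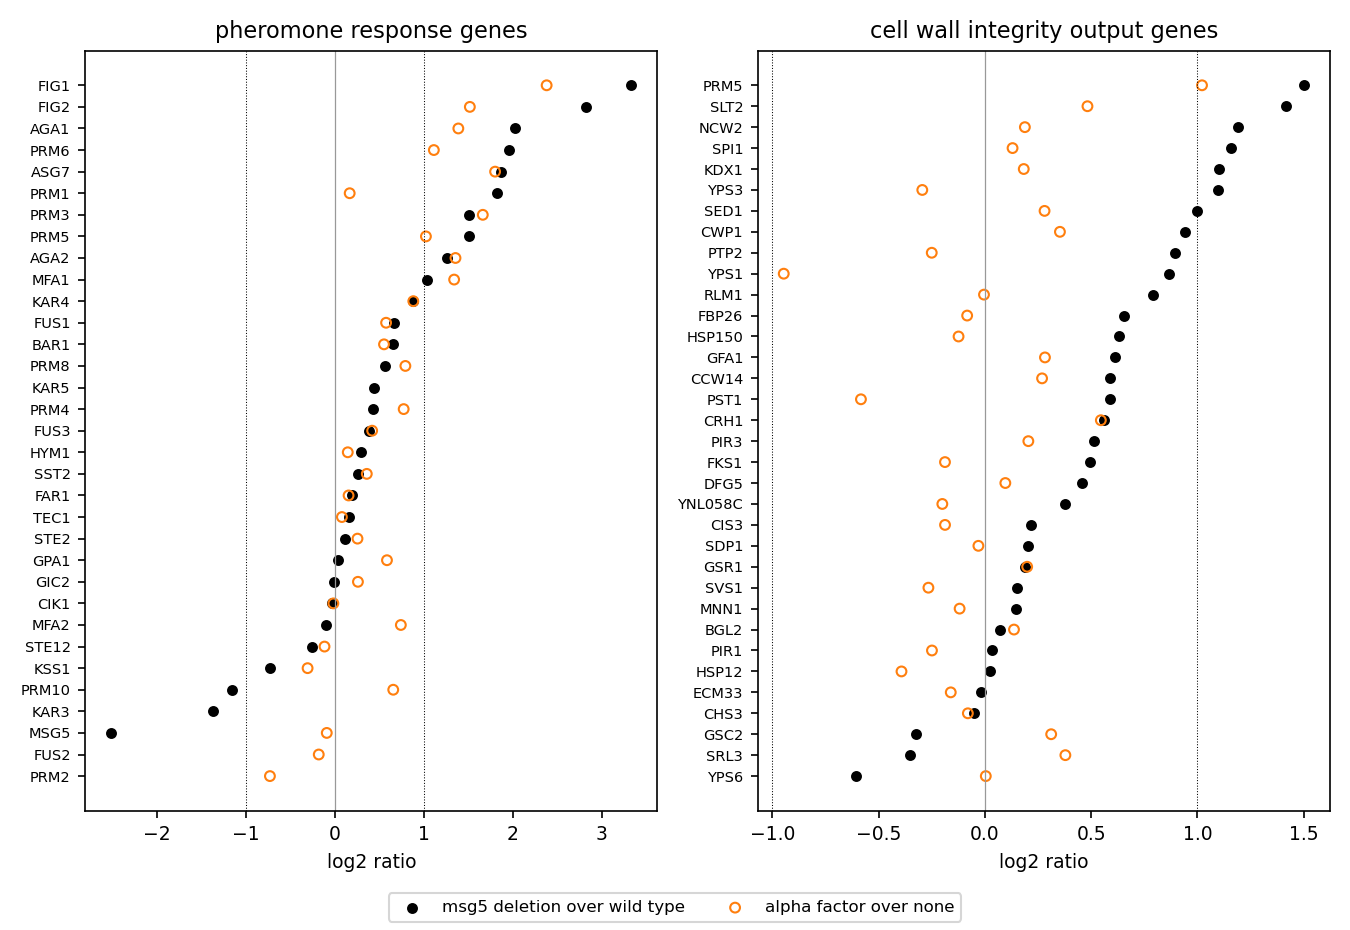
Log2 ratios of the measured pheromone response genes (left) and cell wall integrity output genes (right), one line per gene, for the deletion over wild type (filled) and alpha factor over none (open). Dotted lines mark a 2-fold change, and FIG1 stands at 3.33 and 2.38 while SLT2 stands at 1.42 and 0.48.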

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

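The tests on gene length, on feature order, on the relation between the comparisons and on the lowest features were chosen only after the results were seen. Features without a gene symbol stand outside the gene counts, and 4 of those beyond 2-fold have not been given above. In the deletion comparison YFL-TYA, a Ty feature, had a value of 1.05 and YML048W-A 1.23. With alpha factor YGR114C stood at -1.25 and YLL037W at 1.07.

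Stress and respiration lists lay high and ribosome biogenesis low in the deletion. A gained or lost chromosome is argued against, since the largest distance of any chromosome's median from that of all genes was 0.10. An effect of the deletion on its neighbours is argued against by a largest absolute value of 0.43 among the 4 genes beside MSG5. Slower growth of 1 culture could account for ribosome biogenesis genes at percentile 0 and general stress genes at 100, but ribosomal proteins at percentile 90.5 did not go with it, and no growth rates were used here, so this cannot be told apart. A response to the loss of MSG5 itself stays open.

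With alpha factor, G2/M genes lay at percentile 0.46, which is what an arrest in G1 would give and was set as its test before the data were examined. The arrest is therefore a candidate explanation for the low G2/M list, as a hypothesis. M/G1 genes also lay low with alpha factor (percentile 0.36), G1/S genes did not (percentile 91.9), and neither list was part of that test. Whether an arrest would give these values too was not set out beforehand, so the G2/M list alone cannot settle the explanation. G2/M genes also lay low in the deletion without alpha factor, at percentile 0.01, so the list is not specific to the treatment. Gene length may account for the calls of subtelomeric families and amino acid starvation genes, which went to percentiles 92.2 and 4.12 against lists matched on length, and stays open for ribosomal proteins, at 100 against matched lists but 97.2 against the shortest genes. Under the same matching pheromone response genes (percentile 100), histone genes (0), G2/M genes (1.11) and M/G1 genes (1.11) still stood apart.

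Values repeated along the order of features, with a rank correlation of 0.17 in the deletion comparison and 0.14 with alpha factor between features at the same place in successive plate-sized blocks. It was 0.16 and 0.11 at 2 rows and 0.13 and 0.13 at 48 rows, and at most 0.06 and 0.07 over 583 distances away from multiples of 48 rows, so position on the printing plates may add to single values, beside similarity of near neighbours in the order. That position is argued against as the source of the relation between the comparisons, as r was 0.19 after adjustment for it. Of the 12 lowest features with alpha factor, 12 stayed at or below -1. An effect shared by features at the same place was thus too small to make these low by itself. The adjustment removes only such a shared effect, so it could not test other faults of printing. The same untreated deletion RNA in both comparisons is argued against by the labels alone, which give those cultures growth before time 0 that differs by 90 min. With the direction used here, shared RNA would also give a negative relation, not the positive one seen. Of 4 overlapping or near-identical partners of YGR160W, PMA2, YDL023C and YBL100C, 0 lay at or below -1, a limit set with these values already seen. NSR1 (0.11), GPD1 (-0.09) and ATP1 (-0.39) argue against the partners' transcripts as the sole source for YGR160W, YDL023C and YBL100C. PMA1, the partner of PMA2, lay at -0.95, and only 33 features with alpha factor lay at or below -0.9. For PMA2 the partner's transcript thus stays open. Faults of single spots were not tested.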

How the results depend on the processing

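Matching on gene length, adjustment for position in the cycle of plate-sized blocks and leaving out MSG5 were chosen only after the results were seen, and the other alternatives beforehand. Centring shifts all genes alike and cannot move a percentile. Of 393 list alternatives, 375 kept their state, called or uncalled, as did 512 of 524 gene values. MSG5 stayed on its side of the 2-fold rule in both comparisons. To begin with, 12 of 24 lists in the deletion and 16 of 25 with alpha factor were uncalled, as were many named genes. These shares therefore do not measure how stable a call is. For lists and genes that stayed uncalled, the side was not compared. The 393 include 49 centred lists that could not change, and the 524 include 262 centred gene values. Under all alternatives run, the pheromone response list kept its call in both comparisons and the cell wall integrity output list kept its call in the deletion. With alpha factor the cell wall integrity output list stayed uncalled.

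Counts of genes followed the size rule. At 1.5-fold, 141 genes were higher and 153 lower in the deletion, and 67 and 145 with alpha factor. At 3-fold the counts were 7 and 2 genes, and 3 and 1. At 3 robust SDs they were 147 and 79 genes, and 61 and 61. The other 24 count alternatives stayed within 1.5 times.

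In the deletion, filamentation genes went to percentile 1.94 without the largest member, on the other side of the median. The middle of the list has a gap between PHD1 (-0.23) and NFG1 (0.12). Leaving out any member above that gap moves the median to PHD1, so the change says nothing about PTP2 itself. Cell wall integrity pathway components went to percentile 99.4 by the mean and 98.1 after position adjustment. By the mean, histone genes went to 2.85 and glycolysis genes to 97.2. With alpha factor, filamentation genes went to 0.515 without members of other lists, which left 5 genes. After position adjustment osmotic stress genes went to 1.61, glycolysis genes to 1.27 and phosphate genes to 8.02. By the mean, alpha-cell and diploid genes went to 95.2, respiration genes to 98.3 and phosphate genes to 6.91. Phosphate genes went to 8.84 against random lists from genes in both comparisons, and alpha-cell and diploid genes to 61.4 without the largest member. The median of alpha-cell and diploid genes then fell to -0.02, across a gap in the middle of the list. Against lists matched on gene length, pheromone and filamentation pathway components went to 98.5, phosphate genes to 2.68, amino acid starvation genes to 4.12 and subtelomeric families to 92.2. Apart from the jumps of a median without the largest member, the cause of these changes was not tested.

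The relation between the comparisons fell from 0.18 to 0.098 without the pheromone response list, 0.108 without genes beyond 2-fold, 0.110 without the 1% of genes farthest out and 0.106 as Spearman's rho (0.110 after position adjustment), so it rests in large part on the genes with the largest values. Signal over background was not used here, so its limit on single values is unknown.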

Other observations

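The group of Ty features was chosen only after the results were seen. Retrotransposon features lay high in the deletion. Of 24 measured Ty1 and Ty2 features, 24 lay above the median of all features, with a median of 0.56 at percentile 100 of random sets and a range from 0.07 to 1.57. With alpha factor 26 such features had a median of 0.01 (percentile 85.1). The Ty3 features YIL082W and YIL080W were higher in both comparisons, by 2.97 and 2.16 in the deletion and by 1.40 and 1.60 with alpha factor. Copies of an element are nearly identical and bind the same RNA, so these features are not independent measurements.

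On the right arm of chromosome XI, 5 of 85 measured features were at least 2-fold lower with alpha factor, of 18 such features in all, where 0.314 would be expected for features spread evenly. The arm's median was -0.04. These features were DAL80, CAF4, YSR3, DYN1 and VBA5, all among the 12 lowest named above. Whether their low values share a source was not tested. The arm was picked from the list of lowest features, so this count is no test.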
